A study of Homo sapiens with 20 samples.

How the data were processed

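Peripheral blood mononuclear cells of 4 healthy donors were exposed in culture for 3 h to medium alone, to whole smoke conditioned medium (WSCM) of a reference cigarette at 0.3, 1.0 or 3.0 µg/ml equi-nicotine units, or to a smokeless tobacco extract (STE) of a reference moist snuff at 100 µg/ml equi-nicotine units. Total RNA of each culture was hybridized to 1 Affymetrix Human Transcriptome Array 2.0, which gave 20 arrays in 5 groups of 4. Samples were grouped by their titles, which carry the exposure and a number from 1 to 4. That each number stands for 1 donor follows from the titles together with the design text, which describes cells of 4 donors exposed to these preparations.

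The deposited table holds 1 log2 value per feature and array, 70523 features by 20 arrays, with values from 1.59 to 14.26. The submitters' processing notes name Affymetrix Expression Console and RMA (robust multi-array average). The versions, the level of summary and the genome build are not given in the sources used here, so no coordinates are printed. RMA brings the probes of all arrays to 1 distribution before they are summarized, so a change shared by most transcripts is largely hidden in its values; the feature medians of the arrays ran from 5.01 to 5.22. It also compresses differences among dim features. Of 187 gene changes, not all of them printed below, those other than dose slopes were checked for this. Among those checked, 11 have a group under the array median on all 4 of its arrays, so their size is uncertain: CXCL10 at WSCM 1.0, IL1A and CCL7 at WSCM 3.0, IL1A between STE and WSCM 3.0, CD36, FNDC7, IL24, MIR3140 and SPDYA in medium, and CYP1A1 in medium (compared with WSCM 0.3) and in both medium and WSCM 1.0. With values under the median set to it, IL24 at WSCM 0.3 changed by 2.04 and, at WSCM 3.0, MIR3140 by 1.55, IL1A by -4.57 and CCL7 by -3.70; the text gives the others beside their values. Changes with a group under the median on only some of its arrays are not among the 11, and their size is uncertain as well. The slopes of CD36, IL1A, P2RY13 and ACOD1 share these limits. No detection call was used. The arrays were not normalized again for the values reported.

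Gene symbols came from the array annotation and were brought to current names through Entrez identifiers (21497 features) or synonyms (306 features) of the GRCh38.p14 RefSeq annotation, used for names alone. Another 1978 symbols were kept as given. Features with exactly 1 symbol were used (23781), and features with several symbols (1543) or none (45199) were left out of the gene tests. Of several features of a gene, the one with the highest mean log2 value over the 20 arrays was taken. This gave 22411 genes, 528 of them with more than 1 feature. A gene was tested if its value lay above the median of all features of the array in at least 4 of the 20 arrays, whatever their group, which left 15690 genes. Close copies such as HSPA6 and HSPA7, HSPA1A, the metallothioneins, AKR1C1 and AKR1C2, and processed pseudogenes can share probes, so their values may not be separate.

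Differences were estimated with limma 3.58.1 in R 4.3.3 (jsonlite 2.0.0 for the labels), with 5 group means and the donor as a fixed block, all 20 arrays in 1 fit, and 12 residual degrees of freedom. P values are two-sided and were adjusted by Benjamini-Hochberg over the 15690 genes within each of 6 comparisons. A gene was called at an adjusted p under 0.05. The comparisons were each exposure with medium, STE with WSCM 3.0, and a slope per dose step over medium, 0.3, 1.0 and 3.0. The ± values after a gene are standard errors of that fit, from 4 donors per group. The number of arrays limits the precision.

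The pairing by donor was checked on the values. After the group mean was taken out, the correlation between arrays of 1 donor was at least 0.190, 0.201, 0.327 and 0.306 in donors 1 to 4, while its median between donors was -0.141. All 20 arrays were closest to the other arrays of their own number. The correlation within donors estimated by limma was 0.236.

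The procedure was tested on simulated data for WSCM 3.0 against medium, with 15690 simulated genes of which 50 were changed at each of 4 sizes. It called 92% of the genes changed by 0.5 on the log2 scale, 98% of those changed by 1, 100% of those changed by 2 and 100% of those changed by -1. It made 14 false calls, and 0 calls between unchanged groups. The simulated errors were independent between genes and had 1 spread per gene in all groups. Far fewer genes were changed than were called in the real comparison (7706). The simulation therefore does not show how the procedure behaves where these conditions are not met.

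The groups of genes described are 24 fixed lists with 442 distinct genes, 374 of them tested. They cover NRF2 oxidative stress targets, aryl hydrocarbon receptor targets, heat shock and chaperones, metallothioneins and zinc export, the integrated stress response, endoplasmic reticulum chaperones, p53 targets, immediate early genes, inflammatory cytokines and NF-kB targets, interferon-stimulated genes, cytotoxic effector genes, MHC class II and co-stimulation, hypoxia and glycolysis, cholesterol synthesis, proteasome subunits and ribosomal proteins. They also cover markers of T, NK and B cells, monocytes, dendritic cells, platelets, erythroid cells and neutrophils. Each list was tested with camera, at a preset correlation between genes of 0.01 and with adjustment over the 24 lists. It asks whether the genes of a list are shifted up or down relative to the other genes. A list whose genes change strongly in both directions can therefore fail it. The test was repeated with the correlation estimated from the data, and the text names that value as such. The rotation test fry, which asks whether the genes of a list move on balance in 1 direction without comparing them with other genes, was run beside it. The ± value after a list median is the standard deviation of the list's median change over the 4 donors.

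Genes are named by a rule: the 10 highest and 10 lowest changes among called genes with the same sign in 4 donors for WSCM 3.0 and STE against medium, the 5 highest and 5 lowest for the other comparisons, and up to 4 members of each list with the lowest p. Not every gene that the rule picked is printed. The 187 changes were each fitted again with every donor left out in turn, for genes outside the rule after their values were seen. Members that moved against their list, and members given to show a list that did not pass, were named after their values were seen. The groups, comparisons, block, filter, lists, naming rule and alternatives were fixed before the data were examined. The differences between WSCM doses, those between STE and the lower WSCM doses, the tests of transcript classes, the values under the array medians and the simulated overlap of the doses were added after the list results had been seen.

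The alternatives were no donor block or a random one, arrays centred on their medians, cyclic loess, no filter or a stricter one, the mean of a gene's features, every feature tested, a trended and robust spread, only the arrays compared, a 1.5-fold threshold, a slope per µg/ml, and each donor left out in turn. Principal components were taken over the tested genes. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.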

Results

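Gene expression was measured in 20 cultures of human peripheral blood mononuclear cells, a mixture of T, B and NK cells, monocytes and some dendritic cells. The design asks how the cells respond to 2 tobacco preparations within 3 h: WSCM, which is culture medium through which smoke of the 3R4F reference cigarette was passed, and STE, an extract of the 2S3 reference moist snuff in phosphate buffer. Each of 4 donors gave 1 culture in medium, 1 at each of 3 WSCM doses, named here WSCM 0.3, WSCM 1.0 and WSCM 3.0 after their nicotine equivalents in µg/ml, and 1 with STE at 100 µg/ml nicotine equivalents. The nicotine doses of WSCM and STE differ, and STE was compared with medium rather than with its buffer, so buffer and extract are not separated. Array medians ranged from 5.01 to 5.22 on the log2 scale. Arrays of 1 group correlated at 0.988 to 0.993 and all arrays at 0.970 or more.

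**Figure D1:**
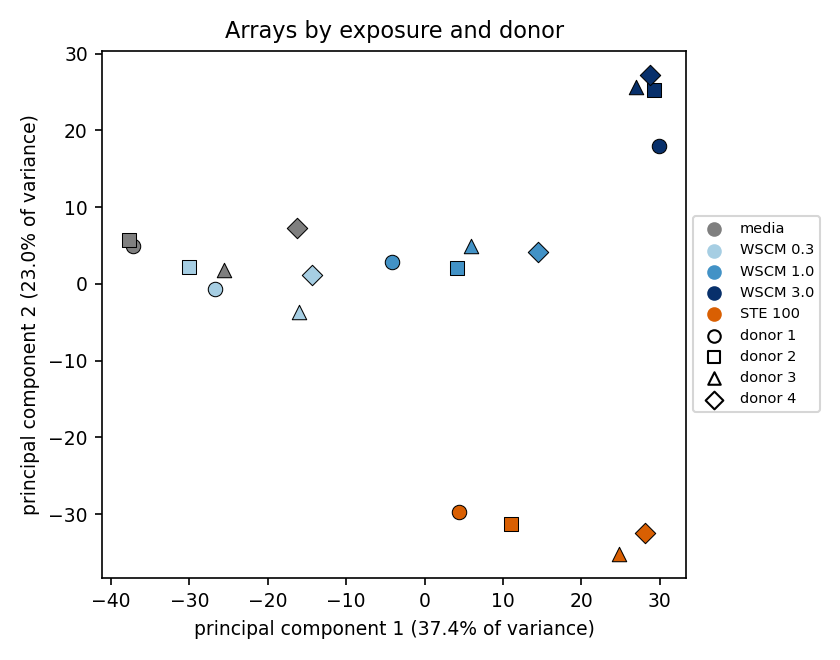
Arrays on principal components 1 (37.4% of the variance) and 2 (23.0%) of the tested genes, colored by exposure, with a symbol shape per donor. The 4 media arrays lie at -37.7 to -16.2 on component 1, the 4 WSCM 3.0 arrays at 27.0 to 30.0, and the 4 STE arrays at -35.2 to -29.8 on component 2.

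At the lowest WSCM dose, genes of xenobiotic and oxidative stress defence rose in all 4 donors. CYP1B1, a cytochrome P450 induced through the aryl hydrocarbon receptor (chromosome 2), rose by 4.36 ± 0.30 on the log2 scale, or 20.5-fold (n = 4 donors, limma adjusted p = 1.2e-06). HMOX1, which degrades heme (chromosome 22), rose 11.6-fold (log2 change 3.54 ± 0.16, adjusted p = 4.9e-09, 4 of 4 donors). GCLM, a subunit of the enzyme that starts glutathione synthesis, rose by 2.31 ± 0.19, the quinone reductase NQO1 by 2.08 ± 0.19, and the cytokine IL24 by 2.55 ± 0.20. Among the genes that fell in 4 of 4 donors, the chemokine CCL22 had a log2 change of -1.73 ± 0.25 (adjusted p = 0.0011) and the formyl peptide receptor FPR2 -1.82 ± 0.30 (adjusted p = 0.0026, or 0.132 without the donor block). KCNJ2 (-1.75) and FFAR2 (-1.57) also fell in 4 of 4 donors. Both lost their limma calls without the donor block (adjusted p = 0.132 and 0.103) and without donor 1 or donor 3. FFAR2 lost its call without donor 2 as well (0.0609).

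Of 25 tested NRF2 targets, genes of the antioxidant response, 20 rose at WSCM 0.3 and 0 fell, and 25 rose adjusted over the list alone. The list median was 0.85 ± 0.17 and positive in 4 of 4 donors (camera adjusted p = 6.8e-42; adjusted p = 3.8e-04 with an estimated correlation). TXNRD1, which reduces thioredoxin, rose by 1.6 ± 0.15. Of 7 aryl hydrocarbon receptor targets, 3 rose over all genes and 3 adjusted over the list alone: CYP1B1, TIPARP (1.17 ± 0.09) and CYP1A1 (0.43 ± 0.06, or 0.19 against the array medians). That list had a median of 0.16 ± 0.13, positive in 4 of 4 donors (camera adjusted p = 3.9e-06; adjusted p = 0.0054 with an estimated correlation). These were the 2 list calls, of 45 in all comparisons, that held with an estimated correlation.

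Another 4 lists passed camera at WSCM 0.3. Of 19 heat shock and chaperone genes, 1 rose, and 2 adjusted over the list alone: DNAJB4, a co-chaperone of HSP70, at 0.87 ± 0.10, was the 1 over all genes. The list median was 0.29 ± 0.11, positive in 4 of 4 donors (adjusted p = 5.6e-05; adjusted p = 0.72 with an estimated correlation). Of 14 genes of the integrated stress response, 0 passed over all genes and 2 rose adjusted over the list alone (median 0.07 ± 0.03 in 4 of 4 donors, adjusted p = 0.024). This call was lost without donor 2 (adjusted p = 0.0587), and its adjusted p = 0.667 with an estimated correlation.

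Of 25 interferon-stimulated genes, 1 fell at WSCM 0.3, and 1 adjusted over the list alone. It was CXCL10, a chemokine that attracts T cells (-2.83 ± 0.69, adjusted p = 0.041 in 4 of 4 donors). CXCL10 did not pass when any 1 of the 4 donors was left out (adjusted p = 0.125, 0.0656, 0.212 and 0.0964 without donors 1 to 4) or without the donor block (0.18). These fits take 1 spread per gene over all 5 groups. The changes of CXCL10 had an SD over donors of 0.75 at WSCM 0.3 and 1.86 at WSCM 1.0. Its standard error at WSCM 0.3 therefore also holds the wider spread at higher doses. GBP1, a guanylate-binding protein, changed by -1.23 ± 0.39 without passing (adjusted p = 0.104). The list median was -0.97 ± 0.39, negative in 4 of 4 donors (camera adjusted p = 3.3e-07; adjusted p = 0.787 with an estimated correlation). Of 15 genes of MHC class II and co-stimulation, 2 fell, and 3 adjusted over the list alone, with a median of -0.12 ± 0.05 in 4 of 4 donors (adjusted p = 0.0011; adjusted p = 0.667 with an estimated correlation). The 2 were the co-stimulatory molecules CD80 (-0.70 ± 0.15) and CD40 (-0.47 ± 0.11), which passed neither without donor 1, 2 or 3 (adjusted p 0.0609 to 0.197) nor without the donor block (0.182 and 0.366).

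WSCM 0.3 changed 457 of 15690 genes, 184 higher and 273 lower, and 30 rose and 22 fell at least 2-fold. With arrays centred on their medians the split was 120 higher and 331 lower. The count rests on every donor: it was 143, 262, 148 and 223 without donors 1, 2, 3 and 4. It was 132 without the donor block and 2474 when only the 8 arrays of the 2 groups were fitted. The main fit takes the spread of a gene over all 5 groups, and the fit of 8 arrays takes it from these 2 groups alone. The calls at WSCM 0.3 thus depend strongly on whether the groups share 1 spread. More genes were higher than lower without donor 1 (80 and 63), without donor 3 (98 and 50) and without the donor block (83 and 49).

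At WSCM 1.0, heat shock genes rose and inflammatory genes fell. HMOX1 rose by 3.46 ± 0.16 (adjusted p = 3.4e-09, 4 of 4 donors). DCSTAMP, a membrane protein of cell fusion in the myeloid lineage, rose by 3.45 ± 0.17, ZFAND2A, a proteasome-associated stress protein, by 2.62 ± 0.19, and the growth factor HBEGF by 2.46 ± 0.28. HSPA7, a close copy of HSPA6 whose probes may not separate them, rose by 2.79 ± 0.20. CXCL10 changed by -6.25 ± 0.69, its mean at WSCM 1.0 (4.48) lying under the array medians, against which the change was -5.61, and ACOD1, which makes itaconate in activated macrophages, by -5.48 ± 0.41 (adjusted p = 1.8e-07, 4 of 4 donors). The chemokine CCL2 changed by -4.37 ± 0.55, the cytokine IL6 by -3.60 ± 0.48 and the potassium channel KCNJ2 by -3.60 ± 0.37.

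All 19 tested heat shock and chaperone genes rose at WSCM 1.0, and 19 adjusted over the list alone, with a list median of 1.76 ± 0.07, positive in 4 of 4 donors (camera adjusted p = 3.4e-20; adjusted p = 0.148 with an estimated correlation). HSPA6 rose by 2.30 ± 0.14, CHORDC1 by 1.90 ± 0.12, DNAJB4 by 1.79 ± 0.10 and FKBP4 by 1.76 ± 0.12. Of 25 NRF2 targets, 12 rose and 0 fell, with the same counts adjusted over the list alone. Their median was 0.30 ± 0.22 in 4 of 4 donors (adjusted p = 1.9e-06; adjusted p = 0.207 with an estimated correlation), with BLVRB, a biliverdin reductase, at 1.07 ± 0.10 and FTL, the ferritin light chain, at 0.49 ± 0.05. Of 7 aryl hydrocarbon receptor targets, 4 rose, and 4 adjusted over the list alone, namely CYP1B1 (2.31 ± 0.30), TIPARP (1.15 ± 0.09), NEDD9 (0.55 ± 0.08) and CYP1A1 (0.19 ± 0.06). CYP1A1 lay under the array medians in both groups, with a change of 0.05 against them. It did not pass without donor 1, 2 or 3 (adjusted p = 0.0927, 0.159 and 0.067), without the donor block (0.0639) or with arrays centred on their medians (0.0887). This list had a median of 0.19 ± 0.12 in 4 of 4 donors (adjusted p = 0.0099; adjusted p = 0.187 with an estimated correlation).

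Of 24 inflammatory cytokines and NF-kB targets, 23 fell at WSCM 1.0 and 0 rose, with the same counts adjusted over the list alone. Their median was -2.02 ± 0.69, negative in 4 of 4 donors (adjusted p = 2.9e-12; adjusted p = 0.292 with an estimated correlation). NFKBIA, an inhibitor of NF-kB, changed by -1.36 ± 0.10, the adhesion molecule ICAM1 by -2.07 ± 0.16 and TNFAIP6 by -2.63 ± 0.26. Of 25 interferon-stimulated genes, 22 fell, and 24 adjusted over the list alone, among them GBP1 (-2.78 ± 0.39), OAS1 (-2.42 ± 0.41) and IRF7 (-1.02 ± 0.15). Their median was -2.09 ± 1.41, negative in 4 of 4 donors (adjusted p = 6.2e-08; adjusted p = 0.533 with an estimated correlation). Of 28 proteasome subunits, 21 fell, and 24 adjusted over the list alone, with PSMA6 at -1.28 ± 0.15 and PSMD4 at -0.51 ± 0.07. The median was -0.33 ± 0.13 in 4 of 4 donors (adjusted p = 8.5e-07; adjusted p = 0.533 with an estimated correlation).

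Another 5 lists passed camera at WSCM 1.0. Of 8 metallothionein and zinc export genes, 7 fell and 0 rose, and 7 fell and 1 rose adjusted over the list alone, with MT2A at -1.50 ± 0.30. Their median was -0.56 ± 0.28 in 4 of 4 donors (adjusted p = 0.014, or 0.0595 without donor 1; adjusted p = 0.533 with an estimated correlation). Of 21 immediate early genes, 10 rose and 3 fell, and 10 rose and 4 fell adjusted over the list alone. FOSB (1.54 ± 0.16) and FOSL1 (0.97 ± 0.11), both partners of JUN in AP-1, rose, while MYC (-1.36 ± 0.15), IER3 (-0.85 ± 0.17) and JUNB (-0.58 ± 0.12) fell. The median was 0.22 ± 0.32, positive in 3 of 4 donors (adjusted p = 0.029, but 0.0833 without donor 3 and 0.256 without donor 4, where the median was 0.13 and 0.08, and with a median of 0.33 and 0.34 without donors 1 and 2; adjusted p = 0.621 with an estimated correlation).

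Of 15 genes of MHC class II and co-stimulation, 6 fell at WSCM 1.0, and 6 adjusted over the list alone, with CD80 at -1.46 ± 0.15 and CD40 at -0.86 ± 0.11. The median was -0.24 ± 0.13 in 4 of 4 donors (adjusted p = 0.022, 0.0824 without donor 1, where the median was -0.15, and 0.106 without the donor block; adjusted p = 0.537 with an estimated correlation). Of 14 T cell markers, 7 fell, and 8 adjusted over the list alone, with the homing receptor CCR7 at -1.25 ± 0.17, CD2 at -1.15 ± 0.16 and CD8A at -0.64 ± 0.09. The median was -0.29 ± 0.11 in 4 of 4 donors (adjusted p = 0.0099, or 0.0567 without the donor block; adjusted p = 0.544 with an estimated correlation). Of 12 platelet markers, 5 fell, and 6 adjusted over the list alone, with the platelet tubulin TUBB1 at -0.83 ± 0.12. The median was -0.14 ± 0.10 in 4 of 4 donors (adjusted p = 0.0099, or 0.0561 without the donor block; adjusted p = 0.292 with an estimated correlation).

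WSCM 1.0 changed 5623 of 15690 genes, 2297 higher and 3326 lower, of which 5312 had 1 sign in all 4 donors. With arrays centred on their medians the split was 1741 higher and 4115 lower.

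At WSCM 3.0, cytokine and chemokine transcripts fell and several genes of myeloid cells rose. P2RY13, a receptor for ADP (chromosome 3), rose by 2.86 ± 0.17, MNDA, a nuclear protein of myeloid cells, by 2.16 ± 0.31, the kinase LRRK2 by 2.02 ± 0.14, and NAIP, a sensor of the inflammasome, by 2.00 ± 0.09 (adjusted p = 4.3e-10), each in 4 of 4 donors. POLG2, a subunit of the mitochondrial DNA polymerase, rose by 2.44 ± 0.25, the cell cycle regulator SPDYA by 2.09 ± 0.31 (1.14 against the array medians) and HBEGF by 1.98 ± 0.28. The microRNA clusters MIR3153 (2.68 ± 0.25) and MIR3140 (2.07 ± 0.20) and the small nucleolar RNA SNORD14E (2.32 ± 0.27) also rose. ACOD1 changed by -6.16 ± 0.41, the cytokine IL1A by -5.57 ± 0.45, CXCL10 by -5.48 ± 0.69, the chemokine CCL20 by -5.27 ± 0.37, and OLR1, a receptor for oxidized lipoprotein, by -5.25 ± 0.25 (adjusted p = 6.5e-10). At WSCM 3.0 the values of ACOD1 (4.99 to 5.29) and CXCL10 (4.77 to 5.79) lay on both sides of the array medians (5.12 to 5.16). So did the values of P2RY13 in medium (4.73 to 5.18, with array medians of 5.01 to 5.09) and of SLC7A11 at WSCM 3.0 (4.70 to 6.14). The size of all these changes is therefore also uncertain. CCL2 (-5.15 ± 0.55), IL6 (-4.43 ± 0.48), CCL4 (-4.05 ± 0.51), CCL7 (-3.99 ± 0.62) and the cystine transporter SLC7A11 (-4.20 ± 0.25) fell as well, all in 4 of 4 donors.

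All 24 tested inflammatory cytokines and NF-kB targets fell at WSCM 3.0, and 24 adjusted over the list alone. Their median was -3.12 ± 1.00, negative in 4 of 4 donors (adjusted p = 1.0e-13; adjusted p = 0.49 with an estimated correlation), with CXCL2 at -3.72 ± 0.19 and CXCL8, a chemokine for neutrophils, at -3.68 ± 0.22. All 25 interferon-stimulated genes fell, and 25 adjusted over the list alone, with OASL at -3.39 ± 0.36 and IRF7 at -1.11 ± 0.15. The median was -2.0 ± 1.29 in 4 of 4 donors (adjusted p = 7.7e-07; adjusted p = 0.723 with an estimated correlation). Of 28 proteasome subunits, 22 fell, and 23 adjusted over the list alone, with PSMC4 at -1.04 ± 0.09. The median was -0.39 ± 0.13 in 4 of 4 donors (adjusted p = 7.7e-07; adjusted p = 0.716 with an estimated correlation). Of 14 genes of cholesterol synthesis, 9 fell and 2 rose, with the same counts adjusted over the list alone, and INSIG1, which restrains sterol synthesis, was at -1.15 ± 0.11 and the reductase DHCR7 at -0.88 ± 0.08. The 2 that rose were IDI1 (1.17 ± 0.17) and FDPS (0.19 ± 0.05). The median was -0.39 ± 0.09 in 4 of 4 donors (adjusted p = 0.038; adjusted p = 0.642 with an estimated correlation). The cholesterol call was lost without donor 3 (0.0742), without the donor block (0.0626) and with arrays centred on their medians (0.0793).

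Of 14 monocyte markers, 12 rose at WSCM 3.0 and 1 fell, with the same counts adjusted over the list alone. The scavenger receptors CD36 (1.56 ± 0.13, or 0.88 against the array medians) and CD163 (1.07 ± 0.11) and the calcium-binding protein S100A9 (1.13 ± 0.11) rose, and MS4A7, a membrane protein of monocytes and macrophages, fell (-1.6 ± 0.23). The median was 0.88 ± 0.16, positive in 4 of 4 donors (adjusted p = 1.7e-04; adjusted p = 0.642 with an estimated correlation). Of 14 T cell markers, 7 fell and 2 rose, and of 13 NK cell markers, 7 fell and 3 rose, with the same counts adjusted over the list alone. The T cell median was -0.45 ± 0.30 and the NK cell median -0.45 ± 0.21, each negative in 4 of 4 donors, and neither list passed camera (adjusted p = 0.0861 and 0.239). Of 12 platelet markers, 9 fell, and 9 adjusted over the list alone, with the integrin ITGB3 at -0.88 ± 0.09, TUBB1 at -1.06 ± 0.12 and the platelet chemokine PPBP at -1.23 ± 0.18. Their median was -0.24 ± 0.02 in 4 of 4 donors (adjusted p = 0.0041; adjusted p = 0.49 with an estimated correlation).

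Stress lists that passed at lower doses did not pass at WSCM 3.0. Of 25 NRF2 targets, 8 rose and 8 fell (camera adjusted p = 0.663), with HMOX1 at 0.56 ± 0.16 (adjusted p = 0.0893 without donor 1), BLVRB at 0.92 ± 0.10, GCLM at -2.18 ± 0.19 and TXNRD1 at -1.07 ± 0.15. Of 19 heat shock genes, 3 rose and 5 fell (adjusted p = 0.663), and HSPA6 was at 0.24 ± 0.14 without passing. Tested directly, 21 of 25 NRF2 targets were lower and 2 higher at 3.0 than at 0.3, with a median of -1.03 ± 0.10, negative in 4 of 4 donors (adjusted p = 4.0e-10; adjusted p = 0.145 with an estimated correlation). All 19 heat shock genes were lower at 3.0 than at 1.0, with a median of -1.47 ± 0.34, negative in 4 of 4 donors (adjusted p = 2.9e-19; adjusted p = 0.0855 with an estimated correlation).

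WSCM 3.0 changed 7706 of 15690 genes, 3771 higher and 3935 lower, and 192 rose and 521 fell at least 2-fold. With arrays centred on their medians the split was 2635 higher and 4940 lower. The doses share the media arrays. Of the genes called at 1.0 and 3.0, 3589 moved in 1 direction and 415 in opposite directions, against 1386 and 1375 if the lists were independent. For 0.3 and 3.0 these counts were 246 and 83, against 113 and 112, and 226 genes were called in 1 direction at all 3 doses, against 21. In 20 simulations of unchanged groups with shared media arrays each count was 0. With no gene changed few can be called at all, so the simulations cannot tell how much shared media arrays add to the overlap of long lists.

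**Figure D2:**
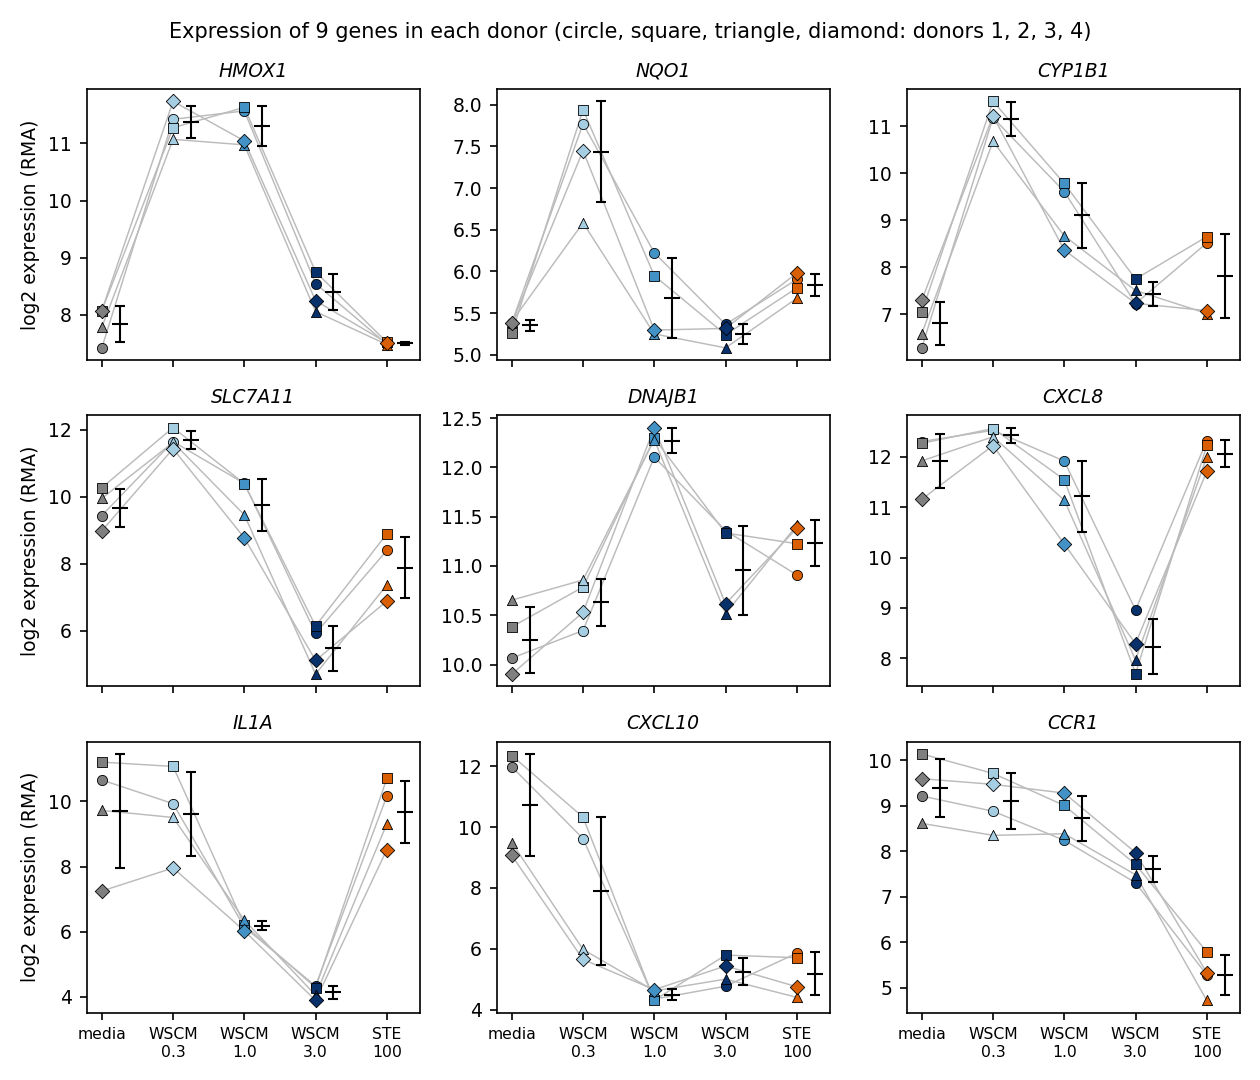
Log2 expression of 9 genes in the 5 groups, with 1 symbol shape and line per donor, and the mean and standard deviation of 4 donors in black beside the points. Against medium, HMOX1 was higher by 3.54 at WSCM 0.3 and by 0.56 at WSCM 3.0, and CXCL8 fell by 3.68 at WSCM 3.0.

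In slopes over medium and the 3 WSCM doses, cytokine, interferon and proteasome genes fell and monocyte markers rose. At WSCM 0.3 itself the inflammatory list (1 higher and 1 lower of 24, adjusted p = 0.452), the proteasome list (1 lower of 28, adjusted p = 0.257) and the monocyte list (0 called of 14, adjusted p = 0.332) did not pass against medium. P2RY13 rose by 1.01 ± 0.05 on the log2 scale per step (adjusted p = 9.4e-10, 4 of 4 donors), and POLG2 by 0.84 ± 0.08. ACOD1 had a slope of -2.26 ± 0.13, IL1A of -2.01 ± 0.14 and CCL20 of -1.84 ± 0.12, each in 4 of 4 donors. All 24 inflammatory genes had a negative slope that passed, and 24 adjusted over the list alone, with a median of -1.19 ± 0.36 in 4 of 4 donors (adjusted p = 3.0e-14; adjusted p = 0.452 with an estimated correlation). A negative slope need not be a fall at each step. CXCL8 was higher at WSCM 0.3 (12.2 to 12.6 over donors) than in medium (11.2 to 12.3) in 4 of 4 donors. All 25 interferon-stimulated genes fell, and 25 adjusted over the list alone (median -0.70 ± 0.51 in 4 of 4 donors, adjusted p = 5.0e-07; adjusted p = 0.758 with an estimated correlation). Between WSCM 3.0 and 1.0 the difference in the interferon list did not pass: 2 genes were lower and 0 higher at 3.0, with a median of 0.03 ± 0.18 (adjusted p = 0.493). Nor did the proteasome list between these doses (8 lower and 4 higher, median -0.13 ± 0.25 in 2 of 4 donors, adjusted p = 0.16) or the platelet list (2 lower of 12, median -0.09 ± 0.11 in 3 of 4 donors, adjusted p = 0.16). Of 28 proteasome subunits 24 fell, and 24 adjusted over the list alone, with PSMC4 at -0.36 ± 0.03 (median -0.14 ± 0.03 in 4 of 4 donors, adjusted p = 1.6e-07; adjusted p = 0.758 with an estimated correlation). Of 14 monocyte markers 11 rose and 1 fell, with the same counts adjusted over the list alone and CD36 at 0.53 ± 0.04 (median 0.29 ± 0.06 in 4 of 4 donors, adjusted p = 1.4e-04; adjusted p = 0.758 with an estimated correlation). Of 12 platelet markers 9 fell, and 9 adjusted over the list alone, with ITGB3 at -0.31 ± 0.03 (median -0.09 ± 0.01 in 4 of 4 donors, adjusted p = 0.0017; adjusted p = 0.452 with an estimated correlation). The slope passed for 7866 genes, 3829 rising and 4037 falling, and for 2849 and 5254 with arrays centred on their medians.

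After STE, genes of the early response and of the integrated stress response rose, and monocyte and interferon genes fell. HSPA2, a chaperone of the HSP70 family (chromosome 14), rose by 3.67 ± 0.16 (adjusted p = 3.6e-10), the Ras-like GTPase RASD1 by 3.48 ± 0.22, ATP1B2, a subunit of the sodium pump, by 3.24 ± 0.17, and the kinase PLK2 by 2.78 ± 0.24, each in 4 of 4 donors. FNDC7 (2.94 ± 0.12, or 1.75 against the array medians), IQCN (2.80 ± 0.15), the histone gene H2BC17 (2.71 ± 0.20), the pseudogene ZSCAN12P1 (3.75 ± 0.21), the microRNA cluster MIR3143 (3.38 ± 0.19) and the small nucleolar RNA SNORD75 (2.73 ± 0.26) also rose. CXCL10 changed by -5.55 ± 0.69, the chemokine receptor CCR1 by -4.11 ± 0.17 (adjusted p = 2.6e-10), CCL2 by -4.04 ± 0.55, GBP1 by -3.74 ± 0.39, CCL7 by -3.73 ± 0.62 and FPR2 by -3.56 ± 0.30. SAMD9L (-3.26 ± 0.53), the monocyte genes MS4A7 (-3.15 ± 0.23) and CD300E (-3.07 ± 0.15), and TNFSF10, the death ligand TRAIL (-3.03 ± 0.46), also fell, all in 4 of 4 donors. Background probe sets without a human target and with 17 to 24 G or C bases were higher after STE by 0.32 ± 0.20 (SD, n = 4 donors).

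The median change of all genes after STE was 0.07, and -0.06 with arrays centred on their medians, a shift of -0.126; the list results that passed for STE kept their directions on that scale. Of 14 genes of the integrated stress response, 7 rose and 0 fell, with the same counts adjusted over the list alone. CHAC1, which degrades glutathione, rose by 1.58 ± 0.15, the transcription factors DDIT3 by 1.88 ± 0.26 and ATF4 by 0.69 ± 0.07, and SESN2 by 0.50 ± 0.06. The median was 0.30 ± 0.13 in 4 of 4 donors (adjusted p = 0.028; adjusted p = 0.75 with an estimated correlation), and 0.17 without donor 4. Of 21 immediate early genes, 14 rose and 1 fell, and 15 rose and 1 fell adjusted over the list alone, with FOSB at 1.56 ± 0.16, KLF4 at 1.07 ± 0.09 and JUN at 1.05 ± 0.13; the 1 that fell was KLF6 (-0.24 ± 0.07; adjusted p = 0.0583 without donor 3). The median was 0.70 ± 0.35 in 4 of 4 donors (adjusted p = 6.0e-04; adjusted p = 0.802 with an estimated correlation).

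Of 25 interferon-stimulated genes, 18 fell after STE, and 18 adjusted over the list alone, with OAS1 at -2.62 ± 0.41 and XAF1 at -2.38 ± 0.41. The median was -1.99 ± 1.54, negative in 4 of 4 donors (adjusted p = 6.0e-05; adjusted p = 0.853 with an estimated correlation). Of 28 proteasome subunits, 26 fell, and 27 adjusted over the list alone, with PSMD1 at -1.16 ± 0.11 and PSMA1 at -0.94 ± 0.09. The median was -0.69 ± 0.18 in 4 of 4 donors (adjusted p = 6.4e-11; adjusted p = 0.75 with an estimated correlation). Of 15 genes of MHC class II and co-stimulation, 11 fell, and 12 adjusted over the list alone, with CD80 at -1.08 ± 0.15 and HLA-DMA, which loads peptides on class II molecules, at -0.78 ± 0.12. The median was -0.44 ± 0.15 in 4 of 4 donors (adjusted p = 0.0032; adjusted p = 0.75 with an estimated correlation).

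Of 14 monocyte markers, 11 fell after STE and 0 rose, and 12 fell adjusted over the list alone, with the proteoglycan VCAN at -0.93 ± 0.14 and the lysosomal protein CD68 at -0.86 ± 0.10. The median was -0.70 ± 0.27 in 4 of 4 donors (adjusted p = 3.4e-04; adjusted p = 0.75 with an estimated correlation). Of 13 NK cell markers, 9 fell and 1 rose, with the same counts adjusted over the list alone, with the receptor KLRC1 at -0.82 ± 0.10 and the adaptor SH2D1B at -1.45 ± 0.21, while NCR3 rose by 0.30 ± 0.10 (adjusted p = 0.0643 without donor 4). The median was -0.56 ± 0.08 in 4 of 4 donors (adjusted p = 0.013, or 0.222 without the donor block; adjusted p = 0.802 with an estimated correlation).

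Inflammatory cytokines and NF-kB targets did not pass as a list after STE: of 24 genes, 3 rose and 6 fell, and 1 rose and 5 fell adjusted over the list alone (adjusted p = 0.48). IL23A (1.08 ± 0.13), TNF (0.98 ± 0.37) and CXCL2 (0.48 ± 0.19) rose. TNF, higher in 3 of 4 donors, did not pass without donor 3 or 4 (adjusted p = 0.137 and 0.268, at 0.42 without donor 4), nor CXCL2 without donor 1, 3 or 4 (0.0569, 0.0517 and 0.254, at 0.19 without donor 4). CXCL8 was at 0.15 ± 0.22 and IL1A at -0.03 ± 0.45, neither passing. NRF2 targets did not pass either, with 5 higher and 4 lower of 25 (adjusted p = 0.989), HMOX1 at -0.34 ± 0.16 without passing and NQO1 at 0.49 ± 0.19, whose call was lost without donor 1, 2 or 4 (adjusted p = 0.0957, 0.0742 and 0.113). Tested directly, 19 of 25 NRF2 targets were lower and 0 higher after STE than at WSCM 0.3, with a median of -0.81 ± 0.08 in 4 of 4 donors (adjusted p = 9.0e-12; adjusted p = 0.0881 with an estimated correlation). CYP1B1 (1.01 ± 0.30) and TIPARP (0.83 ± 0.09) rose after STE, though the aryl hydrocarbon receptor list did not pass (3 of 7 higher, adjusted p = 0.322). CYP1B1 was higher in 3 of 4 donors, at 0.61 without donor 1, and did not pass without donor 1 or 2 (adjusted p = 0.107 and 0.0826). STE changed 9489 of 15690 genes, 5072 higher and 4417 lower; the split was 2185 and 5706 with arrays centred on their medians and 3109 and 4871 with cyclic loess.

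**Figure D3:**
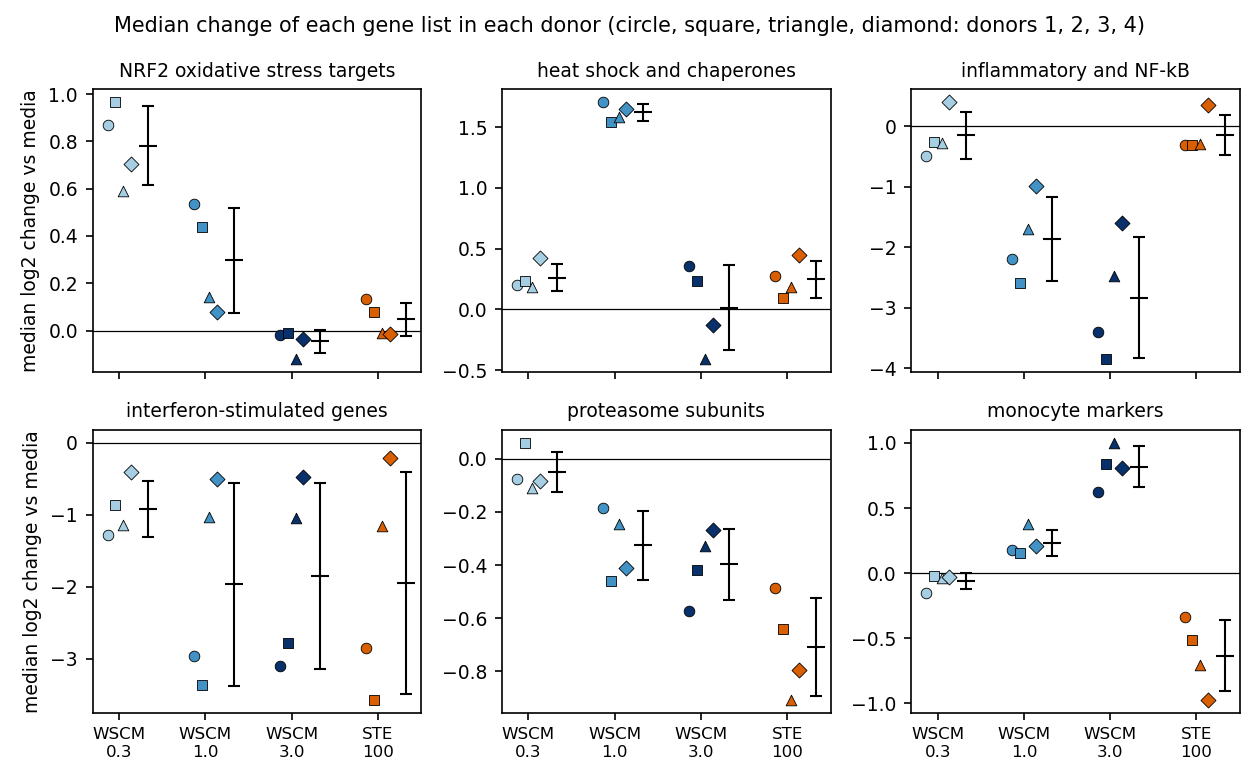
Median log2 change against medium of 6 gene lists, with 1 symbol per donor and the mean and standard deviation of the 4 donors in black. Monocyte markers lie above 0 in 4 of 4 donors at WSCM 3.0 and below 0 in 4 of 4 after STE, and heat shock genes are highest at WSCM 1.0.

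STE and WSCM 3.0 were compared directly, at their different nicotine doses. CCL20 was higher after STE by 6.08 ± 0.37 on the log2 scale, IL1A by 5.54 ± 0.45 (4.54 against the array medians, under which it lay at WSCM 3.0), ACOD1 by 4.42 ± 0.41, CXCL2 by 4.20 ± 0.19 (adjusted p = 2.0e-10) and OLR1 by 4.05 ± 0.25, each in 4 of 4 donors. FGL2, a fibrinogen-like protein of macrophages and T cells, differed by -2.83 ± 0.17, P2RY13 by -2.80 ± 0.17, MNDA by -2.54 ± 0.31, CCR1 by -2.34 ± 0.17 and the adaptor SCIMP by -2.30 ± 0.13, each lower after STE in 4 of 4 donors. P2RY13 and CCR1 after STE lay on both sides of the array medians, as did ACOD1 at WSCM 3.0. The size of their differences is uncertain. Of 24 inflammatory genes, 21 were higher after STE and 0 lower, with the same counts adjusted over the list alone and a median of 2.39 ± 0.33 in 4 of 4 donors (adjusted p = 2.2e-10; adjusted p = 0.336 with an estimated correlation). All 14 monocyte markers were lower, and 14 adjusted over the list alone, with S100A8 at -1.49 ± 0.09, VCAN at -1.99 ± 0.14 and the lectin CLEC7A at -2.14 ± 0.17 (median -1.50 ± 0.37 in 4 of 4 donors, adjusted p = 2.2e-10; adjusted p = 0.194 with an estimated correlation). Of 12 platelet markers 11 were higher, and 11 adjusted over the list alone, with PPBP at 1.43 ± 0.18 (median 0.35 ± 0.05 in 4 of 4 donors, adjusted p = 2.5e-04; adjusted p = 0.194 with an estimated correlation).

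Of 14 genes of the integrated stress response, 8 were higher after STE than WSCM 3.0, and 8 adjusted over the list alone, with CHAC1 at 1.66 ± 0.15 and SESN2 at 1.14 ± 0.06 (median 0.25 ± 0.19 in 4 of 4 donors, adjusted p = 0.0029; adjusted p = 0.296 with an estimated correlation). Of 21 immediate early genes, 13 were higher and 3 lower, with the same counts adjusted over the list alone, with IER3 at 2.28 ± 0.17 and MYC at 1.59 ± 0.15 (median 0.51 ± 0.34 in 4 of 4 donors, adjusted p = 0.011; adjusted p = 0.705 with an estimated correlation). Of 14 endoplasmic reticulum chaperones, 10 were higher and 3 lower, with the same counts adjusted over the list alone, with HYOU1 at 0.84 ± 0.06 and HSPA5, the chaperone BiP, at 0.78 ± 0.09. The median was 0.43 ± 0.03 in 4 of 4 donors (adjusted p = 0.046; adjusted p = 0.369 with an estimated correlation), a call lost without donor 1 (0.0605), without donor 4 (0.0527) and without the donor block (0.0503). Of 14 cholesterol genes, 8 were higher and 1 lower, with the same counts adjusted over the list alone and INSIG1 at 1.63 ± 0.11. Their median was 0.21 ± 0.07 in 4 of 4 donors (adjusted p = 0.045, 0.0559 without donor 3 and 0.057 without the donor block; adjusted p = 0.412 with an estimated correlation).

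Lower after STE than WSCM 3.0 were 10 of 15 genes of MHC class II and co-stimulation, with 3 higher, and 11 lower and 3 higher adjusted over the list alone. HLA-DMB was at -1.29 ± 0.12 and HLA-DMA at -1.34 ± 0.12, while CD40 (0.91 ± 0.11), CD83 (0.76 ± 0.12) and CD80 (0.68 ± 0.15) were higher, and the median was -0.42 ± 0.19 in 4 of 4 donors (adjusted p = 0.021, or 0.0658 without donor 4; adjusted p = 0.568 with an estimated correlation). Of 28 proteasome subunits, 15 were lower and 4 higher, with the same counts adjusted over the list alone and PSMB3 at -1.10 ± 0.13 (median -0.22 ± 0.25 in 3 of 4 donors, -0.12 without donor 3, adjusted p = 0.011, or 0.0658 without donor 4; adjusted p = 0.807 with an estimated correlation). Of 9 dendritic cell markers, 5 were lower, and 5 adjusted over the list alone, with the lectin CLEC10A at -0.94 ± 0.08 (median -0.28 ± 0.19 in 4 of 4 donors, adjusted p = 0.021, or 0.057 without the donor block; adjusted p = 0.296 with an estimated correlation). In all, 8007 of 15690 genes differed, 4073 higher after STE and 3934 lower; more were lower than higher with arrays centred on their medians (3129 higher, 4407 lower) and with cyclic loess (3657 and 4162).

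Changes after WSCM 3.0 and STE were set side by side, with the limit that both use the same media arrays. CXCL10, CCL2 and CCL7 fell and HSPA2 rose after both. In all, 1989 genes were higher in both and 2492 lower in both, against 1219 and 1108 if the lists were independent. A further 480 were higher after WSCM 3.0 and lower after STE, and 350 the reverse, against 1062 and 1272. These 830 genes of opposite direction were 532 without donor 3 and 523 without donor 4. Of the genes called in both, 2691 also differed between the preparations, 1861 of them with changes in 1 direction. The correlation of the changes across genes, which are not independent replicates, was 0.551, against 0.498 in 20 simulations of unchanged groups with shared controls. The covariance was 0.129 against 0.00447, and with WSCM and STE taken from different donors its median was 0.125 and the correlation 0.365 to 0.567. The simulations called at most 1 gene higher and 0 lower in both. Since no gene was changed in them, few could be called, so these counts are no measure for the overlap of the long lists.

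**Figure D4:**
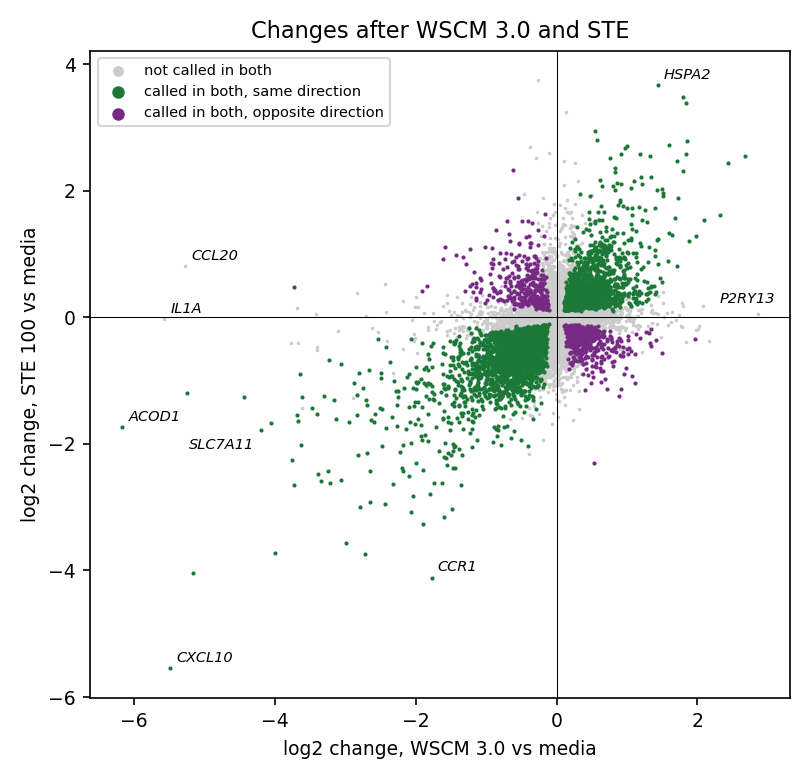
Log2 change against medium of each tested gene after WSCM 3.0 (horizontal axis) and STE (vertical axis), with genes called in both colored by whether their directions were the same. CXCL10 lies at -5.48 and -5.55, and IL1A at -5.57 and -0.03.

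The rotation test fry called 2 lists at WSCM 0.3, those of NRF2 and the aryl hydrocarbon receptor, 13 at WSCM 1.0, 17 at WSCM 3.0 and 12 after STE. It called 14 for STE against WSCM 3.0 and 19 for the dose slope. The mixed form of fry, which asks whether genes of a list change in either direction, called more. In the same order it called 7, 20, 23, 23, 22 and 23 of 24 lists.

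The remaining 7 lists did not pass camera in any of the 6 comparisons. Of 17 p53 targets, 7 rose and 5 fell after STE and 3 rose and 6 fell at WSCM 3.0 (lowest adjusted p over the comparisons 0.368), with the same counts adjusted over the list alone. Of 14 cytotoxic effector genes, 5 fell and 0 rose after STE (lowest adjusted p 0.0569). Of 17 genes of hypoxia and glycolysis, 8 fell and 3 rose at WSCM 3.0 (lowest adjusted p 0.0741). Of 24 ribosomal proteins, 4 rose and 0 fell after STE, and 2 rose adjusted over the list alone (lowest adjusted p 0.0745). Of 12 B cell markers, 5 rose and 1 fell after STE (lowest adjusted p 0.142). Of 11 neutrophil markers, 6 rose and 1 fell at WSCM 3.0 (lowest adjusted p 0.0858). Of 3 tested erythroid markers, 1 rose after STE, and 3 adjusted over the list alone (lowest adjusted p 0.209), the 1 being SELENBP1 (0.21 ± 0.06; adjusted p = 0.0706 without donor 1). In 19 of the list results the median, mean and camera direction differed in sign, among them NRF2 targets after STE (median 0.06, mean -0.08), and 0 of these passed. The list medians of NRF2, aryl hydrocarbon receptor, p53, ribosomal and neutrophil genes after STE turned negative with arrays centred on their medians, none of them a list that passed there.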

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

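The test of monocyte loss at WSCM 3.0, both tests of background hybridization, the reading of the hybridization controls and both tests of the gap between monocyte markers were chosen only after the results they measure were seen. The contrasts between WSCM doses and the grouping of transcripts by class were also chosen after the results had been seen.

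A donor's change lay far from those of the other donors in 10 of 256 sets of 4 changes, by Dixon's test at its 95% critical value. Chance alone gives about 1 in 20 such sets. At WSCM 3.0, MIR3140 changed by 1.16 in donor 3 and by 2.28 to 2.47 in the others. NAIP changed by 2.36 in donor 4 and by 1.86 to 1.92 in the others. CCL20 changed by -3.24 in donor 4 and by -6.05 to -5.88 in the others, and STARD4 by -1.53 in donor 2 and by -1.13 to -1.12 in the others. Between STE and WSCM 3.0, CCL20 differed by 5.66 in donor 4 and by 6.11 to 6.28 in the others. For CCL20, donor 4 thus stood apart mainly in the comparison with medium. ATF3 at WSCM 0.3 changed by 0.89 in donor 4 and by 0.41 to 0.46 in the others, and CYP1A1 at WSCM 1.0 by 0.34 in donor 2 and by 0.12 to 0.15 in the others. After STE, CD80 changed by -0.33 in donor 4 and by -1.36 to -1.29 in the others, and HLA-DRB1 by -0.17 in donor 1 and by -0.82 to -0.71 in the others. Between STE and WSCM 3.0, FCER1A differed by -1.09 in donor 4 and by -0.56 to -0.53 in the others, and TUBB1 by 1.72 in donor 2 and by 0.85 to 1.00 in the others.

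Signals outside the gene tests also stood above medium. Background probe sets with 17 to 24 G or C bases, which match no human transcript, rose after STE by 0.322 (range over donors 0.0579 to 0.532). Of 45168 features without a gene symbol, with the control probe sets of the array left out, 9301 passed at WSCM 3.0, 6549 higher and 2752 lower. After STE 11814 of them passed, 8806 higher and 3008 lower.

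Targets of NRF2 were lower at WSCM 3.0 than at WSCM 0.3, by a median of -1.03 over the list. A difference in array medians does not account for it, since 103% of it stayed with arrays centred on their medians (-1.06). The medians of all arrays ran only from 5.01 to 5.22, so centring could hardly have changed it. A shift hidden where RMA gives all arrays 1 distribution is not tested by this. A smaller share of monocyte RNA at 3.0 would lower monocyte markers, but these were higher at 3.0 than at 0.3 by a median of 0.987, with 12 of 14 called higher. The values are relative to the other RNA of a culture, and regulation within monocytes can also move the markers. A loss of monocytes at 3.0 therefore cannot be excluded by them. A complete stop of transcription from the start of exposure at 3.0 stays open: 4 of 79 inducible genes rose at least 2-fold (DDIT3 3.31-fold, FOSB 3.20-fold, FOS 2.77-fold and KLF4 2.63-fold), under the bound of 5 set for the test, and without arrays from the start of exposure a level held over from then cannot be told apart from a new rise. An effect of the dose that ends the NRF2 response within the 3 h may also account for the difference; it was not tested, and no viability measure was analysed here.

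Small nucleolar RNA and microRNA clusters rose after STE (300 of 607 higher, 17 lower, median 0.23) and at WSCM 3.0 (205 higher, 38 lower, median 0.15), with adjusted p = 0.0342 with an estimated correlation after STE and adjusted p = 0.106 with an estimated correlation at WSCM 3.0. A general upward drift of features at that signal level does not account for it, since both medians were at percentile 100 of 10000 random lists matched on mean level, whose highest medians were 0.0975 and 0.0510. Array scaling does not account for all of it either, since with arrays centred on their medians the rise was 0.108 ± 0.0446 (SD over donors) after STE and 0.0725 ± 0.0360 at WSCM 3.0. For STE, stronger hybridization of GC-rich probes is a candidate cause, since the background probe sets rose by 0.322 ± 0.196, more than the clusters did together. MicroRNAs alone rose less than that (median 0.19), but small nucleolar RNAs alone rose more (0.40). The largest rise of a single background probe set after STE was 0.601, above both. The GC content of the cluster probes was not measured. At WSCM 3.0 the background probe sets changed by 0.0485 ± 0.135, with the largest set at 0.521. The hybridization controls bioB, bioC, bioD and cre rose there in 4 of 4 donors, by 0.215 to 0.377. After STE these controls rose in 4 of 4 donors, by 0.149 (cre) to 0.388. A technical rise and a change in the RNAs themselves therefore cannot be told apart at WSCM 3.0.

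Monocyte markers were higher at WSCM 3.0 and lower after STE, which a changed share of monocyte RNA in the cultures could produce if the abundant markers moved alike. Among 6 abundant markers of middle signal, the gap between the highest and lowest change was 0.510 ± 0.220 (SE) at WSCM 3.0 (S100A9 and S100A12) and 0.882 ± 0.235 after STE (S100A9 and CD14), under the bound of 1 set for markers that move apart. Both gaps exceeded their errors, so the markers did not clearly move alike either. The test therefore could not decide. Over all 8 abundant markers the gaps were 1.33 (CD36 and LYZ) and 1.09 (CD36 and CD14), past that bound. CD36 (mean 4.38 in medium, under the array medians) and LYZ (12.7) lie outside the levels of 6 to 12 taken as middle signal. Values of the arrays ran from 1.59 to 14.26, so neither mean lies at those limits. The wider test was set aside after it was seen, and the outcome depends on that choice. A share alone does not account for MS4A7, which fell at WSCM 3.0 (-1.6 ± 0.23) against the other markers and after STE by more than they did (-3.15 ± 0.23), nor for CD300E after STE (-3.07 ± 0.15), where S100A9 changed by -0.14 ± 0.11 without passing (adjusted p = 0.279). Whether the share changed as well cannot be told apart from regulation within monocytes by the abundant markers, since no cell counts were analysed here.

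Called genes were also counted in other splits of the arrays, each with only the arrays compared and the donor block. Such splits mix the groups, so the difference between the real groups enters their error and lowers their calls. The counts therefore cannot show how many genes chance alone would call. In each of the 5 comparisons of 2 groups, 1 of 32 splits of the 8 arrays gave as many as the real one, namely the real one itself; 3 of the 35 splits could not be fitted. The real counts were 2474, 4684, 6605 and 8397 for WSCM 0.3, 1.0, 3.0 and STE against medium and 6913 for STE against WSCM 3.0, and the highest other split gave 0 in each. The 8 splits that part all 4 pairs, the real one among them, also gave at most 0 apart from the real one, but 8 are too few for a share under 0.05. For the dose slope, 1 of 100 orders drawn within donors gave as many as the real 7817, again the real one, and the highest other gave 3574.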

How the results depend on the processing

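The differences between WSCM doses, those between STE and the lower WSCM doses, and the transcript classes were added after the results had been seen; the alternatives in this part were planned. No called list and no named gene result changed sign under the alternatives tabulated for it, and signs of the other called genes were not tabulated; list medians that changed sign with centred arrays belong to lists not called there. Counts of called genes stayed within 1.5 times of those reported, except as follows. For WSCM 0.3 against medium (457), no donor block gave 132, fitting only the arrays compared gave 2474, and leaving out 1 donor gave 143 to 262. The stricter filter gave 6201 for STE against medium, since fewer genes were tested. Testing every feature gave 11380 for WSCM 1.0, 17958 for WSCM 3.0, 22716 for STE, 16823 for STE against WSCM 3.0 and 19226 for the slope, since it adds unnamed features. The 1.5-fold threshold, stricter by construction, gave 139, 1347, 2297, 2373 and 2143 for WSCM 0.3, 1.0, 3.0, STE and STE against WSCM 3.0, and was not run for the slope. Lists called numbered 6, 11, 6, 7, 10 and 5 in the order of WSCM 0.3, 1.0, 3.0, STE, STE against WSCM 3.0 and the slope. With an estimated correlation they numbered 2, 0, 0, 0, 0 and 0. The correlation within the called lists exceeded the preset 0.01, but how much of the loss this explains was not tested. Without the filter 10 lists were called at WSCM 3.0 and 10 for the slope. Leaving out 1 donor gave 6 to 10 lists at WSCM 0.3 and 5 to 8 for the slope. Genes called in opposite directions after WSCM 3.0 and STE (830) numbered 523 to 723 with 1 donor left out. For the changes given here without a reason, the cause was not tested.

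Of 236 named gene results, 15 lost their call without the donor block, 7, 7, 6 and 1 without donors 1 to 4, and 1 with arrays centred on their medians; 10 belong to genes with more than 1 feature, of which 0 had a feature of opposite sign. Of 45 list calls, 8 were lost without the donor block, 3, 1, 3 and 4 without donors 1 to 4, 1 with centred arrays, and 0 without the filter or with the mean of a gene's features. Without the block 1 list gained a call, metallothioneins and zinc export in the WSCM dose trend (median -0.13, adjusted p = 0.0344). A random donor block gave 351, 5353, 7606, 9427, 7955 and 7805 called genes. Signal over background limits the dim genes: the rule that a gene lie above the array median in at least 4 arrays leaves out the dimmer part of the array, and RMA compresses what remains near it.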

Other observations

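The transcript classes were compared after small RNA clusters had been seen among the highest changes. Besides the small RNAs, pseudogene clusters rose more often than they fell. Of 1017 tested, 431 rose and 92 fell at WSCM 3.0 (median 0.15 ± 0.02 SD over donors, camera adjusted p = 3.1e-06; adjusted p = 0.00556 with an estimated correlation). After STE 447 rose and 131 fell (median 0.16 ± 0.03, adjusted p = 5.6e-05; adjusted p = 0.0199 with an estimated correlation). Of 869 long noncoding RNAs, 418 rose and 36 fell after STE (median 0.17 ± 0.02, adjusted p = 4.9e-08; adjusted p = 0.084 with an estimated correlation), beside the rise of 0.322 in GC-rich background probe sets. Of 148 small nucleolar RNAs alone, 96 rose and 1 fell after STE (median 0.40 ± 0.10, adjusted p = 2.0e-09; adjusted p = 0.153 with an estimated correlation). These 3 STE medians exceed in size the shift of -0.126 that centring the arrays on their medians makes.

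Differences between WSCM doses, also compared after the list results were seen, showed lower cholesterol genes at the highest dose. Of 14 tested, 10 were lower and 1 higher at 3.0 than at 1.0 (median -0.63 ± 0.29 in 4 of 4 donors, adjusted p = 1.7e-05; adjusted p = 0.0855 with an estimated correlation). Of 14 endoplasmic reticulum chaperones, 8 were lower and 1 higher at 3.0 than at 1.0 (median -0.24 ± 0.08 in 4 of 4 donors, adjusted p = 0.0064; adjusted p = 0.162 with an estimated correlation). Of 19 heat shock genes, 18 were lower and 0 higher after STE than at WSCM 1.0 (median -1.26 ± 0.15 in 4 of 4 donors, adjusted p = 4.0e-13; adjusted p = 0.262 with an estimated correlation). Of 24 inflammatory genes, 22 were lower and 0 higher at WSCM 1.0 than at 0.3 (median -1.77 ± 0.52 in 4 of 4 donors, adjusted p = 6.8e-14; adjusted p = 0.25 with an estimated correlation).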
